A study of Mus musculus with 8 samples.

How the data were processed

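RNA was sequenced from GFP-positive bone marrow cells sorted from mice carrying the AML410 leukaemia, untreated or given Dox for 2, 4 or 6 days, on the C57BL/6 background. Per the labels' protocols, RNA was extracted with a column kit and libraries were made with a standard Illumina protocol. Strandedness and the aligner are not given in the sources used here, so reads of overlapping genes on opposite strands cannot be separated. Per the file headers, each library's deposited table holds a count and a gene length for each Entrez gene ID, and the counts are whole numbers that were not normalised. The submitters' processing notes name CASAVA 1.8.2, featureCounts, edgeR 3.8.2, limma 3.22.0 and the build mm10, with no settings. The deposited tables hold 12830 genes, and in each of them the third highest of the 8 CPM values is at least 0.501, so genes of low expression had been removed before deposit. A gene silent in all but 1 group can therefore be missing. Gene length is the other deposited column, identical in all tables, and was not used.

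Symbols and coordinates came from the RefSeq annotation of GRCm38.p6, the same build, which matched 12555 of the 12830 gene IDs. The others hold 2.24% of all counts, were tested under their ID and are not named by symbol. All 8 libraries entered 1 fit in R 4.3.3. Genes were filtered with filterByExpr, which removed 500 genes holding 0.0267% of the counts, and libraries were scaled with TMM. The TMM factors were 1.15 and 1.18 (untreated), 0.937 and 1.12 (day 2), 0.983 and 0.972 (day 4) and 0.873 and 0.849 (day 6). The edgeR 4.0.16 quasi-likelihood test (glmQLFit and glmQLFTest) was run with a group means model without covariates, with Benjamini-Hochberg adjustment over the 12330 genes and a threshold of 0.05. The biological coefficient of variation was 8.34%, with 4 residual degrees of freedom and 7.08 prior degrees of freedom, so 2 libraries per group borrow much of their error from other genes. CPM values are counts scaled by TMM to a common library size, and values are the mean ± SD of n = 2 libraries. Standard errors of fold changes were derived from the fold change and its F statistic. The script was tested on simulated data, where among 11964 unchanged genes of the day 6 comparison 10 were called.

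Before the data were examined, the groups, the tests, the alternatives, 28 gene lists of 417 genes (363 of them in the tables) and the rule for named genes were fixed. The lists cover primary granules, secondary and tertiary granules, mature neutrophils, monocytes and macrophages, known PU.1 targets, stem and progenitor genes, S phase, G2 and M phase, ribosome biogenesis, myeloid transcription factors, pattern recognition, Fc receptors and integrins, lysosome, MHC class II, interferon response, p53 targets, cholesterol synthesis, glycolysis, oxidative phosphorylation and immediate early genes. They also cover markers of other cells (erythroid, B, T and NK, mast cell with basophil and eosinophil, megakaryocyte, dendritic, stroma with endothelium) and sex-linked genes. Some genes are in more than 1 list. List tests used camera in limma 3.58.1 with a preset correlation of 0.01, adjusted over the lists and comparisons of 1 family (3 comparisons with untreated, or the successive days). No list call held with an estimated correlation. For the overlap of calls, all 8 libraries were simulated from the untreated means, so that the noise of the shared controls is included.

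Named genes are Spi1, Trp53, the 6 rising and 6 falling genes with the largest fold change in each comparison with untreated, 5 and 5 for successive days, up to 3 called members per main list and 1 per other list. The leading genes needed an adjusted p under 0.05, an average logCPM of at least 3, groups that did not overlap, and a symbol other than that of a predicted gene. Members named because a count within a list was small, such as those that went against their list, were chosen after their values were seen, as were the genes of the closing section. A few genes that the rule selects are not reported here.

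Totals ran from 9262047 to 11213292 counts per library. Where a group had 1 to 3 counts, a ratio is given with its 95% exact counting interval, and where it had 0, a lower bound against a floor of 3 counts over the group. These intervals and floors cover counting error only, since amplified reads are not independent molecules. Within groups the counts varied more than sampling noise over all genes, so no pair was treated as copies of the same library. The mean chi-square over degrees of freedom was 8.36, 150, 5.52 and 3.04 for untreated, day 2, day 4 and day 6. The medians over genes were 1.82, 5.76, 1.18 and 0.716. Genes with large differences raise the means, but the medians too lie above the median that sampling noise gives. The counts were scaled by totals here, so the high share of a single gene in day 2 replicate 1 adds to the day 2 values.

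Alternatives were DESeq2-style size factors (RLE), no filter on low counts, replicate number as a block, each library left out in turn, the compared groups alone, a minimum change of 1.5-fold (glmTreat), limma-voom, DESeq2 1.42.0, and for lists an estimated correlation and scaling by total counts. Scaling by total counts for gene counts and single genes, and robust empirical Bayes, were added after the data had been seen. With groups of 2, no splits of samples into other groups and no test for outlying samples within a group were run.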

Results

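Transcripts were counted in cells of AML410, a mouse acute myeloid leukaemia (AML) with a monosomal karyotype that lacks p53 and carries a short hairpin RNA against PU.1. PU.1, encoded by Spi1, is a transcription factor of myeloid and B cell development. The hairpin was linked to green fluorescent protein (GFP) and was switched off by giving the mice doxycycline (Dox), so endogenous PU.1 could return. GFP-positive bone marrow cells were sorted from untreated leukaemic mice and from mice given Dox for 2, 4 or 6 days. The gate moved with time, from high GFP in untreated mice to high and intermediate at day 2, intermediate at day 4 and low at day 6, so time and gate always changed together. Each of the 4 groups held 2 libraries, which the sample titles call technical replicates while the series design speaks of duplicate mice. The p-values therefore measure only the spread between these samples, which may be technical.

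The untreated libraries held 10253525 and 10110580 counts, the day 2 libraries 9262047 and 9986780, the day 4 libraries 11213292 and 10551450, and the day 6 libraries 10174785 and 10905390. At this depth, simulated counts for day 6 against untreated, fitted over 12161 genes, gave calls for 53.8% of genes changed 1.5-fold, 86.4% of genes changed 2-fold and 90.9% of genes changed 4-fold. Of the simulated genes 11964 were unchanged, whereas 63.6% of genes were called in the real comparison. The adjustment depends on that share, so these figures do not give the sensitivity of the real test. Of the 12330 genes tested, 8025 (65.1%) differed between at least 1 pair of the 4 groups (edgeR quasi-likelihood test, adjusted p under 0.05). The first principal component of log2 counts scaled to library size (CPM) held 80.7% of the variance. Libraries of the same group correlated across genes at 0.990 (untreated), 0.981 (day 2), 0.992 (day 4) and 0.994 (day 6). Day 2 replicate 1 correlated with untreated replicates 1 and 2 at 0.984 and 0.978, and day 2 replicate 2 at 0.984 and 0.983. By this measure the day 2 libraries were about as close to untreated libraries as to each other.

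Spi1, the gene restored in the model (gene 20375, chromosome 2, 91082374 to 91115759, mm10), rose with time on Dox. It stood at 10.6 ± 3.23 CPM (SD, n = 2) in untreated cells, 15.2 ± 0.606 at day 2, 98.4 ± 6.11 at day 4 and 223 ± 8.35 at day 6. The log2 fold change against untreated was 0.52 (SE 0.17) at day 2, which did not pass the test (edgeR adjusted p = 0.103). Without untreated replicate 2 it was 0.87 (edgeR adjusted p = 0.0158), and DESeq2 gave an adjusted p of 0.0439. It was 3.21 (SE 0.14, edgeR adjusted p = 1.57e-08) at day 4 and 4.39 (SE 0.14, edgeR adjusted p = 8.84e-10) at day 6. Trp53, the p53 gene, described as deleted in this leukaemia (gene 22059, chromosome 11, 69580348 to 69591873), still had counts in every library. It stood at 63.8 ± 1.59 CPM in untreated cells and 41.9 ± 1.22 at day 6 (log2 fold change −0.61, edgeR adjusted p = 6.66e-05). Counts over the whole gene do not check the deletion.

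**Figure D1:**
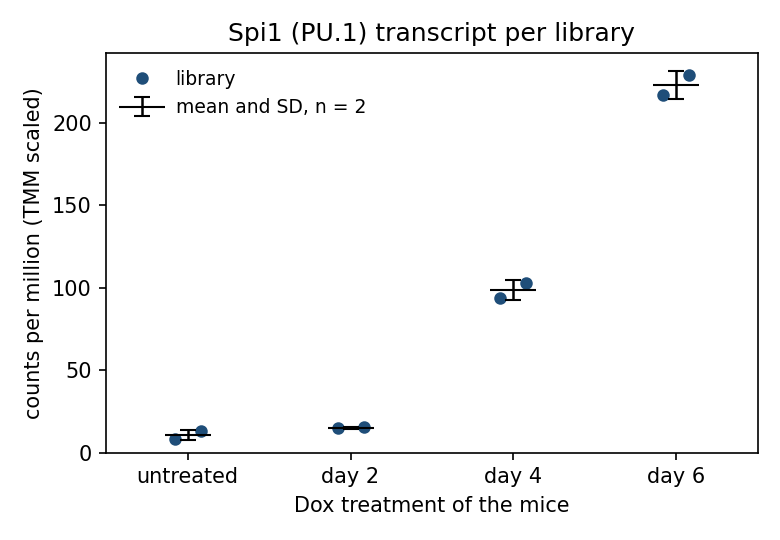
CPM of Spi1 (vertical axis, TMM scaled) in each of the 8 libraries by days of Dox (horizontal axis), with the mean and SD of each group of 2. The day 4 libraries lie at 94.0 and 103 and the day 6 libraries at 217 and 229, above the untreated libraries at 8.34 and 12.9.

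Among the leading rising genes at day 2 were Csf1r, Clec12a and Gpr65, and among the leading falling genes were Adgrg1, Slc29a3 and Myog. Csf1r, the receptor for macrophage colony-stimulating factor (gene 12978, chromosome 18, 61105572 to 61131139), rose from 35.7 ± 5.58 to 109 ± 27.6 CPM (SD, n = 2; log2 fold change 1.61, SE 0.16, edgeR adjusted p = 0.000305). Clec12a, an inhibitory lectin of myeloid cells, rose from 23.5 ± 4.68 to 84.6 ± 6.00 CPM (log2 fold change 1.85, SE 0.12, edgeR adjusted p = 2.50e-05). The proton-sensing receptor gene Gpr65 and the adaptor gene Apba1 rose by 1.64 and 1.60 on the log2 scale. Adgrg1, an adhesion receptor of blood stem and progenitor cells (gene 14766, chromosome 8, 94974756 to 95014208), fell from 41.7 ± 3.02 to 5.56 ± 1.27 CPM (log2 fold change −2.92, SE 0.17, edgeR adjusted p = 1.38e-05). Slc29a3, a nucleoside transporter gene, fell from 109.6 ± 1.07 to 34.5 ± 4.48 CPM. The muscle genes Myog, Tpm2 and Mylpf and the cartilage gene Cnmd also fell, with log2 fold changes of −1.45, −1.26, −1.19 and −1.19. Tpm2 did not pass without untreated replicate 2 (log2 fold change −1.03, edgeR adjusted p = 0.0913).

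Of 16 monocyte and macrophage genes tested, 8 rose and none fell at day 2. The count was 8 when adjusted over the list alone (median log2 fold change 0.68, camera adjusted p = 4.22e-08, adjusted p = 0.212 with an estimated correlation). Known PU.1 targets gave 9 of 21 up and none down, or 12 up and 1 down when adjusted over the list alone (median 0.50, camera adjusted p = 1.01e-09, adjusted p = 0.184 with an estimated correlation). Among them Itgam, the CD11b integrin chain, had a log2 fold change of 0.62 (edgeR adjusted p = 0.0202). It did not pass without untreated replicate 2 (0.57) or without day 2 replicate 2 (0.51), nor under scaling by total counts (0.45). Of 18 myeloid transcription factors 2 rose (Klf4 and Irf5) and 3 fell (Egr1, Junb and Cebpa), also when adjusted over the list alone (median −0.18, camera adjusted p = 0.191, adjusted p = 0.582 with an estimated correlation). The list passed without day 2 replicate 2 (−0.28, camera adjusted p = 0.0215). Irf5 had a log2 fold change of 0.84 (edgeR adjusted p = 0.0196). It likewise did not pass without untreated replicate 2 (0.67) or day 2 replicate 2 (0.50). In the Fc receptor and integrin list 6 of 13 rose, or 8 when adjusted over the list alone (median 0.44, camera adjusted p = 1.96e-09). In the lysosome list 5 of 20 rose, or 9 when adjusted over the list alone (median 0.24, camera adjusted p = 1.85e-06). With an estimated correlation their adjusted p were 0.252 and 0.486. Under scaling by total counts the medians were 0.32 (PU.1 targets), 0.27 (Fc receptors and integrins) and 0.06 (lysosome). Of 18 pattern recognition genes only Tlr9 rose, or 5 up and 3 down when adjusted over the list alone (median 0.26, camera adjusted p = 0.168, adjusted p = 0.762 with an estimated correlation). That list passed without day 2 replicate 1 (0.44, camera adjusted p = 0.00114) and under scaling by total counts (0.09, camera adjusted p = 0.0162). Of 7 primary granule genes 4 rose, namely Prss57, Ms4a3, Prtn3 and Ctsc, of which Ctsc (0.55) was not called under scaling by total counts (0.37). There were 5 up and 1 down when adjusted over the list alone (median 0.55, camera adjusted p = 1.85e-06, adjusted p = 0.291 with an estimated correlation). Of 21 S phase genes 6 rose, among them Pcna, the replication clamp (log2 fold change 0.68). The count was 15 when adjusted over the list alone (median 0.25, or 0.07 under scaling by total counts, camera adjusted p = 2.60e-08, adjusted p = 0.351 with an estimated correlation). Of 13 immediate early genes none rose and 4 fell (Egr1, Junb, Ier3 and Ier2). The count was 5 when adjusted over the list alone (median −0.58, camera adjusted p = 3.15e-06, adjusted p = 0.375 with an estimated correlation). None of 14 stem and progenitor genes and none of 22 ribosome biogenesis genes was called at day 2. The stem and progenitor list held 21 genes, but Meis1, Hoxa5, Hoxa7, Hoxa9, Hoxa10, Mycn and Mecom were not among the deposited genes and could not be assessed. Without untreated replicate 1, Myb (−0.33) and the ribosome biogenesis gene Gnl3 (−0.69) were called. Without untreated replicate 2 the ribosome biogenesis list passed (0.11).

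Other lists also passed at day 2. Of 8 erythroid genes none was called, or 1 fell when adjusted over the list alone (median −1.02, camera adjusted p = 0.0227, adjusted p = 0.524 with an estimated correlation). The list did not pass without untreated replicate 1 (−0.32) or day 2 replicate 2 (−0.44). Of 22 G2 and M phase genes 2 rose (Cdk1 and Aurkb), or 6 when adjusted over the list alone (median 0.18, or 0.00 under scaling by total counts, camera adjusted p = 0.000487, adjusted p = 0.507 with an estimated correlation). The list did not pass without day 2 replicate 2 (0.11). Of 16 cholesterol synthesis genes only Fdps rose, or 2 when adjusted over the list alone (median 0.19, or 0.01 under scaling by total counts, camera adjusted p = 0.00452, adjusted p = 0.613 with an estimated correlation). It did not pass without untreated replicate 2 (0.10) or day 2 replicate 1 (0.18).

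In all, 756 genes (6.13%) changed at day 2, 516 up and 240 down, of which 64 rose and 39 fell by over 2-fold (edgeR quasi-likelihood test). The count was 1325 without untreated replicate 1, 325 without untreated replicate 2, 397 without day 2 replicate 2, 402 without day 6 replicate 1 and 405 without day 6 replicate 2. A test against a minimum change of 1.5-fold left 24 genes. Under scaling by total counts the median of all genes was −0.17, with 170 genes up and 658 down. A single gene took 13.3% of the counts of day 2 replicate 1, which lowers the other genes of that library under this scaling. This bears on all day 2 values given under scaling by total counts.

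Day 2 replicate 1 stood apart in its RNA. A gene with no symbol in the annotation used took 13.3% of its counts (95% exact binomial interval 13.28 to 13.33%) against 0.0883 to 0.149% in the other 7 libraries. Another gene with no symbol took 1.13% of the counts of this library, against 0.00658 to 0.0119% in the others. Lars2 took 1.48%, against 0.0905 to 0.214%. The genes with no symbol were not identified, so the kind of RNA they hold was not tested. Rmrp, the RNA of a mitochondrial RNA processing enzyme, and Lars2 led the rising genes under the rule for named genes (log2 fold change 4.99, SE 1.27, and 2.45, SE 0.65). Both rested on this library, with 0.47 and 0.25 without it. Neither passed without any 1 of the other libraries, apart from day 2 replicate 2. The B cell genes summed to 175 CPM in this library, 28.4 CPM in day 2 replicate 2, and 103 and 52.6 CPM in the untreated libraries. Secondary and tertiary granule genes, of which Pglyrp1 and Camp rose at day 2, had a median of 0.17, or −0.04 under scaling by total counts (camera adjusted p = 0.0147, adjusted p = 0.701 with an estimated correlation). It was 0.02 without this library (camera adjusted p = 0.882) and 0.23 without untreated replicate 2 (camera adjusted p = 0.182). For mature neutrophil genes, of which 4 rose, among them Il1r2, Trem3 and Trem1, the median of 0.53 (camera adjusted p = 0.00286) became 0.05 (camera adjusted p = 0.0926) without it. The adjusted p was 0.572 with an estimated correlation. MHC class II genes had a median of 0.66 (camera adjusted p = 0.0259, adjusted p = 0.372 with an estimated correlation), which was 0.01 without this library and 0.24 without untreated replicate 2, neither called. Without this library 534 genes changed at day 2.

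At day 4, monocyte and macrophage genes, secondary and tertiary granule genes and known PU.1 targets stood above their untreated levels, and part of the progenitor genes stood below. Csf1r had a log2 fold change of 4.68. Itgam rose from 29.8 ± 1.52 to 495 ± 74.5 CPM (SD, n = 2; log2 fold change 4.05, SE 0.13, edgeR adjusted p = 2.85e-09). Clec4a2, an inhibitory C-type lectin, rose from a mean of 3.38 to 226 ± 16.3 CPM (log2 fold change 6.06, SE 0.14, edgeR adjusted p = 2.99e-10). Clec4b1 rose by 5.92 on the log2 scale. Reads of these lectin genes may be shared between copies. Pik3r5, a regulatory subunit of phosphoinositide 3-kinase gamma, rose by 5.85. Hpgd, which inactivates prostaglandins, rose by 6.13 and the SLAM adaptor gene Sh2d1b1 by 6.95. Upb1, an enzyme of pyrimidine breakdown, had 971 counts at day 4 against 3 in untreated cells, a ratio of 360 (95% counting interval 123 to 1750).

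Of 16 monocyte and macrophage genes 12 rose and none fell at day 4, also when adjusted over the list alone (median log2 fold change 3.53, or 3.004 with Ms4a7 at its lower bound, camera adjusted p = 1.61e-13, adjusted p = 0.162 with an estimated correlation). The high-affinity Fc receptor gene Fcgr1 rose from 3.93 ± 0.939 to 73.0 ± 13.2 CPM. The scavenger receptor gene Msr1 had 47 counts against 2 in untreated cells (ratio 26.2, 95% counting interval 6.85 to 222), and Ms4a7, at 0 counts in untreated cells, was at least 5.56-fold higher. Known PU.1 targets gave 18 of 21 up and none down, or 18 up and 1 down when adjusted over the list alone (median 1.92, camera adjusted p = 8.11e-21, adjusted p = 0.162 with an estimated correlation). Secondary and tertiary granule genes gave 12 of 14 up, also when adjusted over the list alone (median 1.93, camera adjusted p = 1.43e-06, adjusted p = 0.424 with an estimated correlation). Chil3, a chitinase-like secreted protein, rose from a mean of 39.4 to 1919 ± 283 CPM. Lactoferrin (Ltf) rose from 36.4 ± 5.29 to 431 ± 134 CPM, and the gelatinase gene Mmp9 by 2.35 on the log2 scale. Mature neutrophil genes gave 15 of 17 up and none down, or 15 up and 1 down when adjusted over the list alone (median 1.90, camera adjusted p = 7.00e-05, adjusted p = 0.486 with an estimated correlation). The formyl peptide receptor gene Fpr1 and Ly6g had log2 fold changes of 3.43 and 3.02. Stfa2l1 had 67 counts against 3 (ratio 24.9, 95% counting interval 8.15 to 124). Over the same interval the B cell genes summed to 32.1 and 36.8 CPM and the erythroid genes to 5.08 and 9.85 CPM, against 103 and 52.6, and 19.8 and 9.48, in untreated cells.

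Pattern recognition genes (16 of 18 up, none down, median 2.30, camera adjusted p = 1.61e-13), Fc receptor and integrin genes (13 of 13 up, median 1.91, camera adjusted p = 1.46e-24) and lysosome genes (17 of 20 up, with Gla down, median 1.44, camera adjusted p = 8.36e-16) rose at day 4. Their adjusted p were 0.184, 0.162 and 0.226 with an estimated correlation. When adjusted over the list alone 16, 13 and 17 rose and 2, 0 and 2 fell. The inhibitory receptor gene Pirb rose from 1.90 ± 0.0804 to 69.7 ± 5.72 CPM. The lysosomal protease gene Ctss rose from 32.3 ± 4.59 to 555 ± 40.3 CPM, and the lectin gene Clec4n, at 0 counts in untreated cells, was at least 34.1-fold higher. Interferon response genes gave 17 of 18 up, also when adjusted over the list alone (median 1.58, camera adjusted p = 4.70e-07, adjusted p = 0.486 with an estimated correlation), led by Ifit3 at a log2 fold change of 3.59. Of 6 MHC class II genes 4 rose (Cd74, H2-DMa, H2-DMb1 and H2-Eb1), also when adjusted over the list alone (median 1.51, camera adjusted p = 0.000754, adjusted p = 0.226 with an estimated correlation).

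Part of the progenitor genes fell at day 4. Of 14 stem and progenitor genes 7 fell (Kit, Myb, Cdk6, Hlf, Myc, Angpt1 and Runx1) and none rose, also when adjusted over the list alone (median −0.82, camera adjusted p = 0.00367, adjusted p = 0.220 with an estimated correlation). Myb, a transcription factor of progenitors (gene 17863, chromosome 10, 21124930 to 21160984), fell from 546 ± 53.2 to 211 ± 19.1 CPM and the cell cycle kinase gene Cdk6 from 115 ± 3.36 to 49.9 ± 3.52 CPM. Of 22 ribosome biogenesis genes 14 fell and none rose, also when adjusted over the list alone (median −0.44, camera adjusted p = 0.00694, adjusted p = 0.747 with an estimated correlation), led by Gnl3 at −1.26. The primary granule genes split. Ctsc and Prss57 rose by 2.43 and 1.79 on the log2 scale and Prtn3 and Ms4a3 by less. Cathepsin G (Ctsg) fell from 5229 ± 270 to 1615 ± 148 CPM and Elane fell (camera adjusted p = 0.264 for the list, adjusted p = 0.825 with an estimated correlation). Of the muscle genes, Myog fell from 67.5 ± 8.71 to 0.708 ± 0.102 CPM (log2 fold change −6.56, SE 0.31, edgeR adjusted p = 2.07e-08), and Mylpf and Tpm2 had log2 fold changes of −4.98 and −4.58. Umodl1 and Cnmd had log2 fold changes of −5.60 and −4.31.

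At day 4, 5924 genes (48.0%) had changed, 3217 up and 2707 down, with 1167 up and 816 down by over 2-fold (edgeR quasi-likelihood test). A minimum change of 1.5-fold left 2062. Scaling by total counts in place of TMM put the median of all genes at −0.27 and gave 1816 up and 4519 down.

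**Figure D2:**
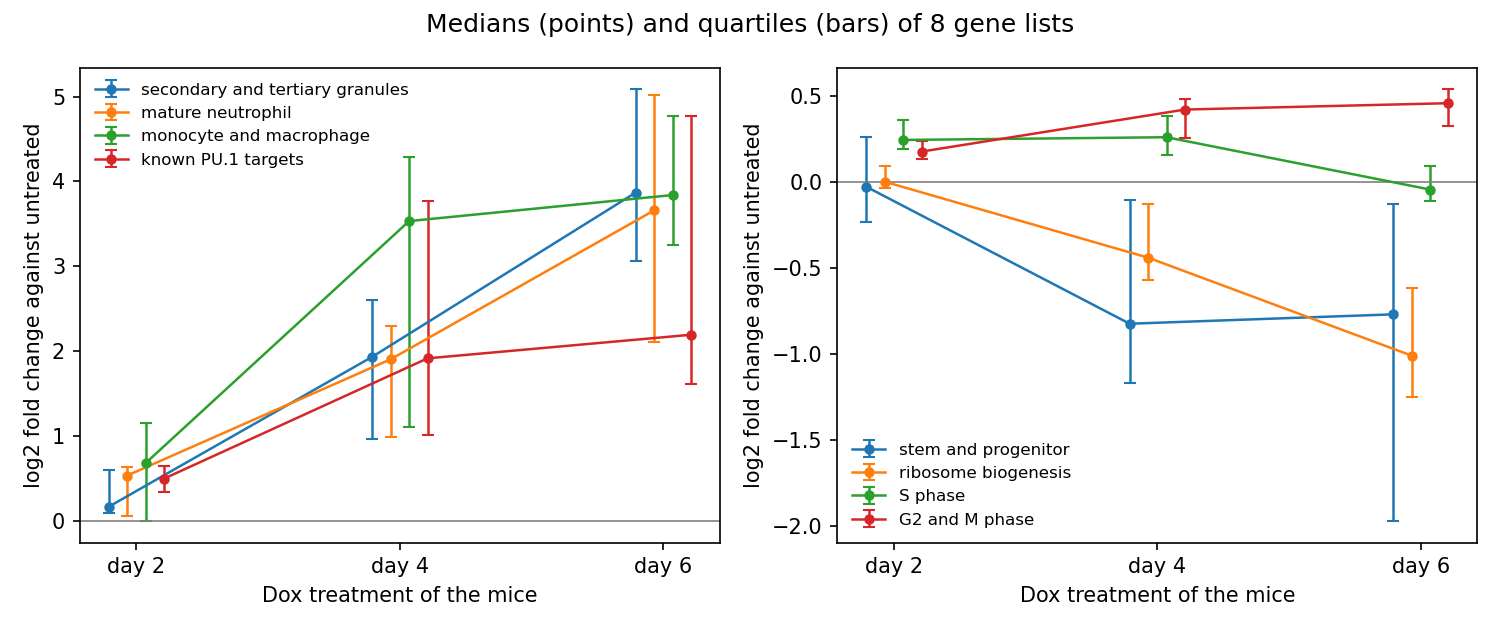
Median log2 fold change against untreated (vertical axis) of 8 gene lists at 2, 4 and 6 days of Dox (horizontal axis), with bars from the first to the third quartile of the list's genes. The monocyte and macrophage median went from 0.68 to 3.53 and 3.84 and the secondary and tertiary granule median from 0.17, which was −0.04 under scaling by total counts, to 1.93 and 3.87.

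At day 6, secondary and tertiary granule genes, monocyte genes and known PU.1 targets stood high together, and ribosome biogenesis genes, muscle genes and part of the progenitor genes stood low. Chil3 (gene 12655, chromosome 3, 106147554 to 106167564) reached 7588 ± 546 CPM (SD, n = 2; log2 fold change 7.59, SE 0.29, edgeR adjusted p = 2.42e-09), and reads shared with its close paralog may add to it. Ltf (gene 17002, chromosome 9, 111019292 to 111042766) reached 4859 ± 1031 CPM (log2 fold change 7.06, SE 0.44, edgeR adjusted p = 9.07e-08) and Mmp9 reached 504 ± 156 CPM. Itgam reached 1677 ± 154 CPM (log2 fold change 5.81, SE 0.14, edgeR adjusted p = 1.92e-10). Sh2d1b1 had a log2 fold change of 7.80. Asprv1, an aspartic protease gene, had 1429 counts against 3 in untreated cells (ratio 622, 95% counting interval 212 to 3020). Upb1 had 1335 against 3 (ratio 581, 198 to 2820) and the lectin gene Clec4b2 676 against 3 (ratio 294, 100 to 1430).

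Of 14 secondary and tertiary granule genes 13 rose at day 6, also when adjusted over the list alone (median log2 fold change 3.87, camera adjusted p = 5.98e-11, adjusted p = 0.291 with an estimated correlation). Mature neutrophil genes gave 16 of 17 up, with Slpi down, the same counts as adjusted over the list alone (median 3.66, camera adjusted p = 1.46e-10, adjusted p = 0.291 with an estimated correlation). They include Fpr1 (log2 fold change 6.63), Ly6g (6.08) and Stfa2l1 (ratio 160, 95% counting interval 54.2 to 778). Of 8 erythroid genes 7 rose in the same samples, also when adjusted over the list alone, to summed levels of 55.2 and 84.0 CPM against 19.8 and 9.48 CPM in untreated cells (median 2.25, camera adjusted p = 0.392, adjusted p = 0.825 with an estimated correlation). Under scaling by total counts the list passed (median 1.82, camera adjusted p = 0.0163). The globin gene Hba-a2, which shares reads with Hba-a1, had a log2 fold change of 2.27 (edgeR adjusted p = 0.00288). It did not pass without day 6 replicate 2 (1.61) or under robust empirical Bayes (2.27, edgeR adjusted p = 0.0539). B cell genes gave 3 up (Dntt, Rag1 and Cd22) and 1 down (Igll1) of 14, also when adjusted over the list alone, with summed levels of 74.5 and 89.2 CPM. Cd22 was not called without untreated replicate 2 (0.46) or day 6 replicate 1 (0.54), nor under scaling by total counts (0.26). Their median was 0.07, or −0.36 under scaling by total counts, while the list test pointed down (camera adjusted p = 0.951, adjusted p = 0.995 with an estimated correlation).

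Monocyte and macrophage genes gave 15 of 16 up at day 6, with Irf8 down, also when adjusted over the list alone (median 3.84, or 3.72 with Ms4a7 at its lower bound, camera adjusted p = 1.21e-10, adjusted p = 0.172 with an estimated correlation). Fcgr1 had a log2 fold change of 5.16, Msr1 a ratio of 90.7 (95% counting interval 24.6 to 757), and Ms4a7 was at least 13.1-fold higher. Known PU.1 targets gave 18 of 21 up, with Nab2 down, also when adjusted over the list alone (median 2.19, camera adjusted p = 8.50e-21, adjusted p = 0.162 with an estimated correlation). Pattern recognition genes (17 of 18 up, median 3.16, camera adjusted p = 6.88e-13), Fc receptor and integrin genes (13 of 13 up, median 2.83, camera adjusted p = 1.45e-23), interferon response genes (18 of 18 up, median 2.68, camera adjusted p = 6.98e-11) and MHC class II genes (6 of 6 up, median 3.13, camera adjusted p = 0.000801) stood high, with the same counts when adjusted over the list alone. Their adjusted p were 0.188, 0.162, 0.351 and 0.220 with an estimated correlation. Clec4n was at least 47.4-fold higher, and Pirb, Ifit3 and Cd74, the MHC class II invariant chain, had log2 fold changes of 5.98, 5.54 and 5.70. Lysosome genes gave 17 of 20 up, with Gla and Gaa down, also when adjusted over the list alone (median 1.56, camera adjusted p = 2.25e-10, adjusted p = 0.332 with an estimated correlation). Ctss had a log2 fold change of 4.66. Of 18 myeloid transcription factors 11 rose and 5 fell (Vdr, Egr1, Irf8, Cebpa and Gfi1), also when adjusted over the list alone (median 0.67, camera adjusted p = 0.103, adjusted p = 0.507 with an estimated correlation). The list passed without day 2 replicate 1 (0.66, camera adjusted p = 0.0361) or day 2 replicate 2 (0.67, camera adjusted p = 0.0323), and under scaling by total counts (0.23, camera adjusted p = 0.0401). Irf5, at a log2 fold change of 4.60, rose furthest.

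Stem and progenitor genes gave 7 of 14 down at day 6 with only Erg up, also when adjusted over the list alone (median −0.77, camera adjusted p = 0.00241, adjusted p = 0.220 with an estimated correlation). The listed Hoxa genes, Meis1, Mycn and Mecom are not covered, since they were not among the deposited genes. Cdk6 and Myb had log2 fold changes of −2.14 and −2.12, while Erg rose from 0.634 ± 0.0666 to 3.25 ± 0.295 CPM. Of 22 ribosome biogenesis genes 20 fell, or 21 when adjusted over the list alone, and none rose (median −1.01, camera adjusted p = 3.05e-06, adjusted p = 0.507 with an estimated correlation), with Gnl3 at −2.20. Primary granule genes gave 3 up (Prss57, Ctsc and Ms4a3) and 3 down (Ctsg, Elane and Prtn3), also when adjusted over the list alone. Ctsg stood at 545 ± 24.4 CPM with a log2 fold change of −3.26 (camera adjusted p = 0.951 for the list, adjusted p = 0.995 with an estimated correlation). Of the muscle genes, Myog fell to 0.218 ± 0.150 CPM (log2 fold change −8.18), and Tpm2 was 207-fold lower (95% counting interval 57.0 to 1710). The collagen chaperone gene Serpinh1 was 381-fold lower (105 to 3150), the growth factor binding protein gene Igfbp7 fell from 139 ± 14.0 to 0.766 ± 0.446 CPM and Umodl1 had a log2 fold change of −7.08.

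Cell cycle genes followed another course, which depended on the scaling. G2 and M phase genes gave 16 of 22 up at day 4 and 18 at day 6 with none down (18 and 18 when adjusted over the list alone), with medians of 0.42 (camera adjusted p = 0.0259) and 0.46, which were 0.17 and 0.03 under scaling by total counts. The day 4 call was lost under that scaling (camera adjusted p = 0.129). With an estimated correlation the adjusted p were 0.701 and 0.762. The day 6 shift was not called, but it passed without untreated replicate 1 (0.48, camera adjusted p = 0.0439) or untreated replicate 2 (0.41, camera adjusted p = 0.0408). Nusap1, a spindle protein gene, rose by 0.89 on the log2 scale at day 6, while Kif20a (0.60) and Ccna2 (0.58) did not pass under scaling by total counts (0.16 and 0.15). S phase genes gave 11 of 21 up and none down at day 4, also when adjusted over the list alone, and 4 up (Pcna, E2f1, Mcm5 and Rrm2) and 3 down (Mcm6, Mcm2 and Chaf1b) at day 6, also when adjusted over the list alone. Their medians were 0.26 and −0.04, or 0.01 and −0.48 under scaling by total counts (camera adjusted p = 0.187 and 0.813, adjusted p = 0.825 and 0.976 with an estimated correlation), and under scaling by total counts E2f1, at 0.43 at day 6, was at −0.01 and Pcna, at 0.61, was not called (0.18).

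Of the metabolic and stress lists none passed at day 6. Oxidative phosphorylation gave 11 of 20 down and 2 up (Sdhb and Uqcrc2), led by Cyc1 at −1.08 (median −0.27, camera adjusted p = 0.123). It passed without untreated replicate 2 (−0.29, camera adjusted p = 0.0311). Cholesterol synthesis gave 4 up, among them Fdps, Fdft1 and Mvd, and 7 down of 16 (median −0.22, camera adjusted p = 0.813). Glycolysis gave 7 up and 2 down (Pfkl and Pgam1) of 16, led by the glucose transporter gene Slc2a3 at 4.18 (median 0.31, or −0.13 under scaling by total counts, camera adjusted p = 0.433). The p53 target list, in a leukaemia described as lacking p53, gave 8 up and 2 down (Cdkn1a and Aen) of 14, led by Perp at 2.69 (median 0.48, camera adjusted p = 0.192). Immediate early genes gave 7 up and 2 down (Egr1 and Ier3) of 13, led by Atf3 at 5.14 (median 0.68, camera adjusted p = 0.235). Under scaling by total counts the medians were −0.70 for oxidative phosphorylation, −0.65 for cholesterol synthesis, 0.04 for p53 targets and 0.24 for immediate early genes. For these 5 lists the counts were the same when adjusted over the list alone. The adjusted p were 0.825, 0.976, 0.881, 0.486 and 0.825 with an estimated correlation. Among markers of other cells, T and NK cell genes gave 1 up (Cd5) and 1 down (Thy1) of 4, and mast cell, basophil and eosinophil genes 3 up (Siglecf, Il5ra and Prss34) and 2 down (Mcpt8 and Hdc) of 9. Megakaryocyte genes gave 3 up (Gp9, Itga2b and Itgb3) and 1 down (Vwf) of 4, dendritic cell genes 3 up (Clec9a, Ccr9 and Siglech) and 1 down (Tcf4) of 5, and stroma and endothelium genes 3 down (Cxcl12, Sparc and Kitl) of 5. All 5 lists had a camera adjusted p of 0.519 or more at day 6, and 0.754 or more with an estimated correlation. Thy1 was not called without untreated replicate 2 (−0.55), day 6 replicate 1 (−0.59) or day 6 replicate 2 (−0.60). Tcf4 was not called without untreated replicate 2 (−0.17) or day 6 replicate 1 (−0.23), nor by DESeq2 (−0.27, DESeq2 adjusted p = 0.0918). Itgb3, at 0.61, was not called under scaling by total counts (0.18). Xist, in untreated cells at 25.5 and 92.7 CPM in the 2 libraries, was the only sex-linked gene tested, with a log2 fold change of −0.92 (edgeR adjusted p = 0.107). Without untreated replicate 1 it was −1.56 (edgeR adjusted p = 0.000846), and under scaling by total counts −1.36 (edgeR adjusted p = 0.000475).

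At day 6, 7839 genes (63.6%) had changed, 3942 up and 3897 down, with 1689 up and 1481 down by over 2-fold (edgeR quasi-likelihood test). A minimum change of 1.5-fold left 3674. Scaling by total counts put the median of all genes at −0.47 and gave 2078 up and 6647 down.

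**Figure D3:**
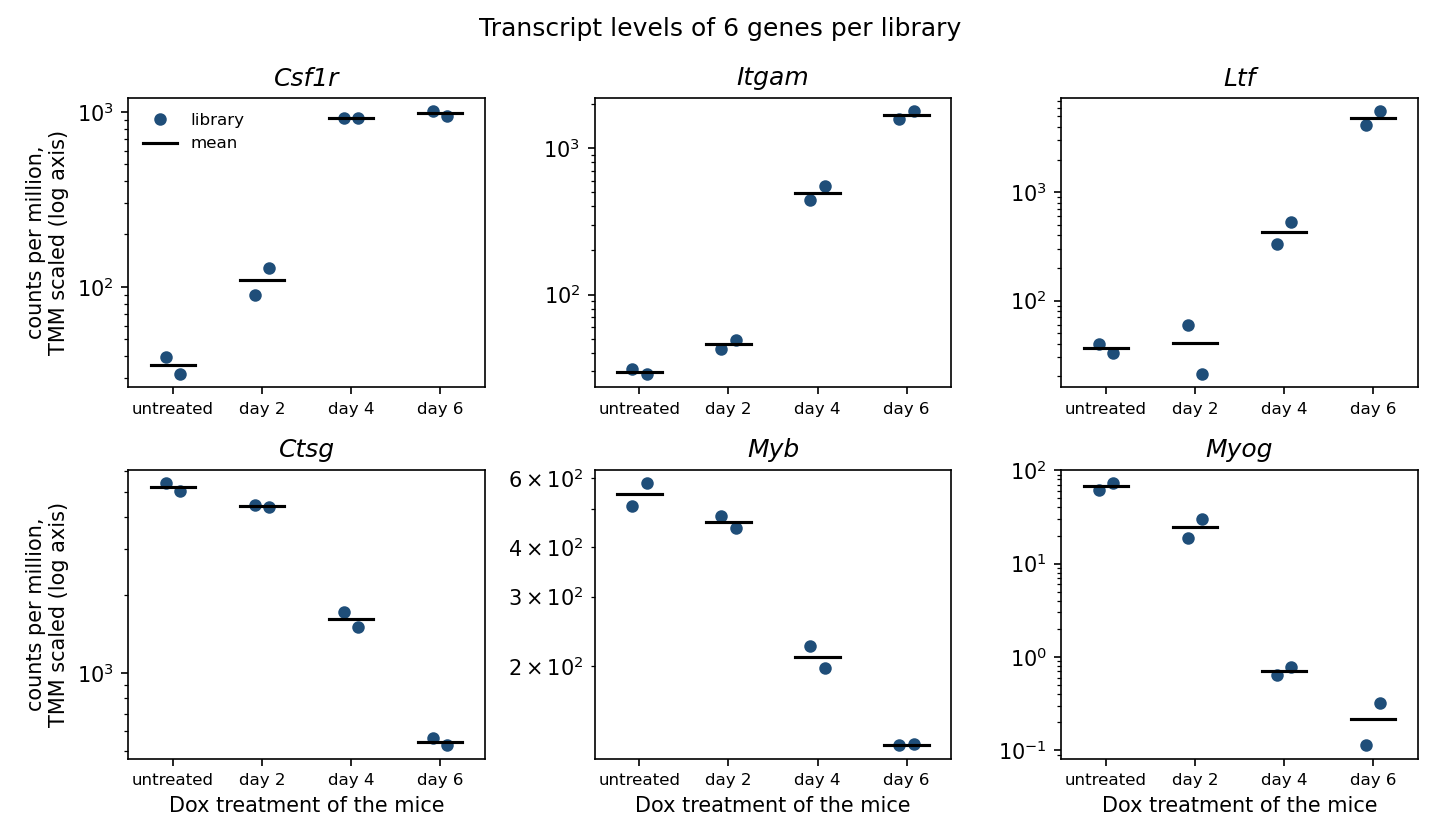
CPM, TMM scaled, on a log axis (vertical) of Csf1r, Itgam, Ltf, Ctsg, Myb and Myog in each library by days of Dox (horizontal), with the mean of each group of 2 as a line. Csf1r lay at 917 and 919 at day 4 and 1008 and 949 at day 6, while Ltf went from 336 and 525 at day 4 to 4130 and 5588 at day 6.

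Monocyte genes and secondary and tertiary granule genes both rose from day 2 to day 4. The latter rose further to day 6, as did known PU.1 targets and interferon response genes, while primary granule genes did not. From day 4 to day 6 the monocyte list also shifted up, by a smaller median (0.37 against 2.13 for secondary and tertiary granules). The difference between the lists was not tested. From day 2 to day 4, monocyte and macrophage genes gave 13 of 16 up and none down, also when adjusted over the list alone (median 2.55, camera adjusted p = 4.75e-13, adjusted p = 0.152 with an estimated correlation). Known PU.1 targets gave 16 of 21 up, or 17 when adjusted over the list alone (median 1.30, camera adjusted p = 9.86e-20, adjusted p = 0.117 with an estimated correlation). Secondary and tertiary granule genes gave 11 of 14 up, also when adjusted over the list alone (median 1.23, camera adjusted p = 1.47e-06, adjusted p = 0.378 with an estimated correlation). Primary granule genes gave 2 up (Prss57 and Ctsc) and 3 down (Elane, Ctsg and Ms4a3) of 7, also when adjusted over the list alone (median −0.21, camera adjusted p = 0.765, adjusted p = 0.943 with an estimated correlation). The call of Prss57 (0.43, edgeR adjusted p = 0.0461) was lost under RLE size factors, the replicate block, total counts (0.36) and DESeq2. It was also lost without day 2 replicate 1 (0.41) or 2 (0.44), day 4 replicate 1 (0.49) or 2 (0.37), or day 6 replicate 1 (0.42) or 2 (0.42). Mature neutrophil genes gave 12 of 17 up, with Slpi down, or 13 up when adjusted over the list alone (median 1.21, camera adjusted p = 0.000479, adjusted p = 0.453 with an estimated correlation). Among the genes that rose furthest were Upb1 (log2 fold change 6.47), the glycosyltransferase gene Galnt9 (6.10), Clec4a3 (5.92) and Hpgd (5.88). Of the genes that the rule for named genes allows, with an average logCPM of at least 3, those that fell furthest were Myog (−5.11), Umodl1 (−4.73) and Mylpf (−3.80), apart from Rpph1 (−5.58) and Rmrp (−5.44). These 2 were at −0.35 and −0.93 without day 2 replicate 1. They also did not pass without day 4 replicate 1 (−5.38 and −4.90) or day 4 replicate 2 (−5.81 and −6.25). In this interval 4640 genes changed, 2681 up and 1959 down, and 1434 passed a test against 1.5-fold (edgeR quasi-likelihood test).

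From day 4 to day 6, secondary and tertiary granule genes gave 13 of 14 up, also when adjusted over the list alone (median 2.13, camera adjusted p = 2.08e-18, adjusted p = 0.192 with an estimated correlation). Mature neutrophil genes gave 16 of 17 up, with Slpi down, also when adjusted over the list alone (median 1.79, camera adjusted p = 9.86e-20, adjusted p = 0.152 with an estimated correlation). Of the genes with an average logCPM of at least 3, Asprv1, Ltf, Chil1, Mmp9 and the phospholipase gene Plbd1 rose furthest, with log2 fold changes of 3.69, 3.50, 3.37, 3.25 and 3.21. Primary granule genes gave 1 up (Prss57) and 3 down (Elane, Prtn3 and Ctsg) of 7, also when adjusted over the list alone (median −0.20, camera adjusted p = 0.00852, adjusted p = 0.453 with an estimated correlation). Erythroid genes gave 6 of 8 up in the same interval, or 7 when adjusted over the list alone (median 3.51, camera adjusted p = 0.000103). B cell genes gave only 3 of 14 up (Rag1, Dntt and Igll1), also when adjusted over the list alone (median 2.05, camera adjusted p = 0.0169). The adjusted p of these 2 lists were 0.272 and 0.736 with an estimated correlation. Monocyte and macrophage genes gave 6 up and 1 down (Irf8) of 16, or 8 up and 2 down when adjusted over the list alone (median 0.37, camera adjusted p = 0.0300, adjusted p = 0.453 with an estimated correlation). Csf1r did not pass the test. S phase genes fell (10 of 21, or 14 when adjusted over the list alone, median −0.26, camera adjusted p = 0.000472). So did ribosome biogenesis genes (19 of 22, or 21 when adjusted over the list alone, median −0.54, camera adjusted p = 1.67e-09) and cholesterol synthesis genes (10 of 16, also when adjusted over the list alone, median −0.45, camera adjusted p = 0.000472), with adjusted p of 0.453, 0.378 and 0.453 with an estimated correlation. Serpinh1 was 39.2-fold lower (95% counting interval 10.6 to 329), Igfbp7, Nwd1 and Heph had log2 fold changes of −4.14, −3.34 and −2.94, and Tpm2 had 2 counts against 20 (8.53-fold lower, 2.07 to 75.2). Tpm2 was not called without day 4 replicate 2 (−2.59), day 6 replicate 1 (−2.99) or day 6 replicate 2 (−2.93). Between these days 3689 genes changed, 1961 up and 1728 down, and 554 passed a test against 1.5-fold (edgeR quasi-likelihood test). Under scaling by total counts the median of all genes was −0.20, with 881 up and 2646 down. The count was 1731 without day 4 replicate 1, 2132 without day 6 replicate 1 and 1726 without day 6 replicate 2.

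Other lists rose from day 4 to day 6 as well. Known PU.1 targets gave 14 of 21 up, or 15 when adjusted over the list alone (median 0.72, camera adjusted p = 3.48e-11), and Fc receptor and integrin genes 10 of 13, or 12 (median 0.77, camera adjusted p = 1.33e-11). Interferon response genes gave 14 of 18 up, or 16 when adjusted over the list alone (median 1.25, camera adjusted p = 2.60e-13), and pattern recognition genes 11 of 18, or 12 (median 0.55, camera adjusted p = 9.08e-06). Immediate early genes gave 8 of 13 up (camera adjusted p = 0.000314) and MHC class II genes 4 of 6 (median 1.43, camera adjusted p = 0.0359), also when adjusted over the list alone. No member of these 6 lists was called down. With an estimated correlation the adjusted p were 0.152, 0.207, 0.272, 0.272, 0.453 and 0.378.

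The days shared many of their calls. Of the 516 genes up at day 2, 472 (91.5%) were up at day 4, where independent lists would share 135, and of the 240 genes down, 192 were down at day 4, against 52.7. Of the 3217 genes up at day 4, 2907 were up at day 6 against 1029 for independent lists, and of the 2707 genes down, 2349 were down against 856, while 37 went the opposite way. Day 2 and day 6 shared 439 up and 176 down, with 53 in opposite directions, and independent lists would share 75.9 of the genes down. All 3 comparisons use the same untreated libraries, which by itself correlates them. Across genes, which are not independent replicates, the covariance of the log2 fold changes was 0.244 (days 2 and 4), 0.277 (days 2 and 6) and 1.42 (days 4 and 6), against 0.0397, 0.0396 and 0.0405 in 20 simulations of 4 unchanged groups. The correlations were 0.54, 0.46 and 0.90 against 0.47, 0.45 and 0.47 in the simulations. The simulated groups did not change, so their correlations hold noise only. They do not show how much of the observed correlations the shared controls give. The untreated group cannot be split into parts of 2 libraries, so part of the excess may come from the shared controls. The change over the first interval and that from day 4 to day 6, which share no library, correlated across the 12330 genes at Pearson 0.12 and Spearman 0.088, and at −0.10 without day 2 replicate 1.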

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

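The tests described in this part, including the splits of the libraries, were chosen after the results were seen. A difference in effect between days drew attention to 178 genes that were higher at day 4 than in untreated cells and then lower at day 6 than at day 4, and to 158 genes that were lower at day 4 and then higher at day 6 (edgeR quasi-likelihood test, each interval adjusted). Independent lists of these sizes would share 451 and 431 genes, and 1221 genes rose and 840 fell over both intervals, so a turn was less frequent than a continued change. The day 4 libraries enter both intervals, so a chance value in them adds to these counts. With a different day 4 library in each interval, 59 and 90 genes rose and fell back in the 2 possible assignments, 36 of them in both, and 60 and 80 fell and came back, 38 of them in both.

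Among the genes that rose and fell back, the protocadherin gene Pcdh18 went from 4.56 ± 1.15 CPM (SD, n = 2) to 24.2 ± 6.29 at day 4 and 7.35 ± 0.759 at day 6, the lipoprotein lipase gene Lpl from 55.0 ± 1.02 to 124 ± 19.0 and 51.2 ± 8.04, and the eosinophil-type ribonuclease gene Rnase2a from a mean of 55.2 to 191 and 86.4. Il6st, the shared receptor chain of the interleukin 6 family, went from 83.9 ± 12.4 to 222 ± 9.78 and 116 ± 11.9. To come back means here only a rise from day 4 to day 6, not a return to the untreated level. Among those that fell and came back, Adgrg1 went from 41.7 ± 3.02 to 2.76 ± 0.725 and 7.77 ± 0.320 CPM. It was still below untreated at day 6 (log2 fold change −2.42). The sulfotransferase gene Chst15 went from 26.4 ± 3.15 to 7.33 ± 3.56 and 38.5 ± 4.73, and Dgat2, which makes triglycerides, from 163.8 ± 4.38 to 80.0 ± 6.25 and 178 ± 26.6.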

How the results depend on the processing

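Scaling by total counts for gene counts and single genes, and robust empirical Bayes, were chosen after the data were seen. The other alternatives were planned. Every count stayed within 1.5 times its value under RLE size factors, no filter, limma-voom, DESeq2, robust empirical Bayes and scaling by total counts, for example 4659 (DESeq2) to 6335 (total counts) at day 4 and 6591 to 8725 at day 6. The direction did not stay: total counts gave 20.5%, 28.7% and 23.8% of calls up at day 2, day 4 and day 6, against 68.3%, 54.3% and 50.3%, and 1870 up and 1921 down from day 2 to day 4. Its median over all genes was −0.17, −0.27 and −0.47 at days 2, 4 and 6. In day 2 replicate 1 a single gene took 13.3% of the counts, which lowers the other genes of that library under scaling by total counts. A minimum change of 1.5-fold, a stricter question by construction, left 24, 2062, 3674, 1434 and 554 genes for day 2, day 4, day 6, day 2 to 4 and day 4 to 6. Fitting the compared groups alone, with fewer samples, gave 232 genes at day 2.

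Leaving out 1 library, which assumes that the lone library varies like the others, gave 325 to 1325 genes at day 2, 4467 to 5985 at day 4, 6405 to 7932 at day 6, 3215 to 5040 from day 2 to 4, 1726 to 4193 from day 4 to 6, and 6510 to 8299 between any groups. At day 6 the G2 and M phase list became called, at 0.41 (without untreated replicate 2) to 0.48 (without untreated replicate 1). The B cell list at day 2 (0.35, not called) was called at −2.10 without day 2 replicate 1 and at 1.32 without day 2 replicate 2. The correlation of the first with the last interval was 0.11 among genes with an average logCPM of at least 3, and −0.10 to 0.17 with 1 library left out, with −0.10 without day 2 replicate 1. Under scaling by total counts E2f1 at day 6 went from 0.43 to −0.00659. The cause was not tested in these cases. With an estimated correlation no list passed: the day 6 medians of 3.87 (secondary and tertiary granules), 3.66 (mature neutrophil), 3.84 (monocyte and macrophage), 2.19 (PU.1 targets) and −0.77 (stem and progenitor) had adjusted p of 0.291, 0.291, 0.172, 0.162 and 0.220.

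Replicate numbers did not pair the libraries: correlations of deviations between same-numbered libraries were 0.21, −0.08, −0.03, −0.07, −0.13 and 0.06 over the 6 pairs of groups. With the replicate number as a block, 612, 5787, 7718, 4501, 3493 and 7864 genes were called at day 2, day 4, day 6, from day 2 to 4, from day 4 to 6 and between any groups. Of 274 values of named genes, 207 called, total counts ended 16 calls and also that of E2f1, whose sign changed, and leaving out 1 library ended 84 of their calls over all 8 fits. Values called neither way changed sign in 50 comparisons for genes and 38 for lists. Depth limits genes near the floor, whose ratios carry wide intervals.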

Other observations

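The tests in this part were chosen after the patterns were seen, though the bounds of the histone test were set before its values were. The muscle list was written after the leading falling genes were seen. Most of the muscle genes found in untreated cells were lower with Dox. Of 35 skeletal muscle genes listed, 17 were in the tables and 16 were tested. At day 2 none rose and 5 fell (Myog, Mylpf, Tpm2, Tnnt3 and Myh3; median log2 fold change −1.02), at day 4 13 fell and 1 rose (Tnni2; median −4.28, or −4.13 with genes at 0 counts at their bound), and at day 6 11 fell and 2 rose (Tnni2 and Tnnt1; median −5.38, or −4.56 at the bound). Single-list camera p were 1.83e-09, 2.54e-09 and 1.61e-06, and 0.0738, 0.0821 and 0.140 with an estimated correlation, and the list holds genes that had led the falling genes, so these are not independent evidence. Myog, the myogenin transcription factor, stood at 61.3 and 73.6 CPM in the untreated libraries, 18.7 and 30.2 at day 2, and 0.113 and 0.324 at day 6. The muscle fusion gene Mymk and the acetylcholine receptor gene Chrng had no counts in the 4 libraries of days 4 and 6. Synpo2, an actin-binding protein of muscle, fell from 345 ± 1.11 (SD, n = 2) to 17.8 ± 0.284 CPM at day 6.

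Cebpe, a regulator of secondary granule genes, stood at 189 ± 23.8 CPM (SD, n = 2) in untreated cells, 139 ± 24.3 at day 4 and 298 ± 42.4 at day 6, whereas Gfi1 went from 180.2 ± 18.6 to 84.1 ± 14.2 and 93.5 ± 0.0140. Klf4, a monocyte regulator, stood at 16.4 ± 1.32, 36.9 ± 9.19, 245 ± 7.63 and 199 ± 7.72 CPM from untreated to day 6, and the chemokine receptor gene Ccr2 at 44.6 ± 11.2, 107 ± 50.8, 1136 ± 86.8 and 1228 ± 76.9. The neutrophil elastase gene Elane stood at 8017 ± 771 CPM in untreated cells and 2790 ± 55.5 at day 6.

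The muscle genes may come from muscle cells carried into the untreated sort. Muscle would bring contractile transcripts far above the regulator Myog, but the highest of 9 contractile genes, Mylpf, stood at 0.662 and 0.710 times Myog in the untreated libraries. For the 9 genes tested, that argues against mature muscle cells. Other contractile genes sought, among them Acta1, Ckm and Myh1, were not among the genes tested. A gene found only in untreated cells can be missing from the deposit, so the ratio does not exclude mature muscle cells. Expression of the muscle genes in the leukaemic cells, and a loss that depends on the gate, stay open as hypotheses.

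The rise of the secondary and tertiary granule genes may reflect other marrow cells entering a gate of lower GFP. At day 4 the higher of the B cell and erythroid medians against untreated was −1.06, but these genes lay near the floor and neither list was called with all libraries. The B cell list was called down without day 2 replicate 1 (−1.96, camera adjusted p = 0.0361) or day 2 replicate 2 (−1.95, camera adjusted p = 0.0254). The erythroid list was not called, and neither list addresses normal myeloid cells, so other marrow cells stay open. One uniform share of cells like day 6 among cells like untreated is opposed at day 4, since the monocyte list would need 84.8% (quartiles 29.3 to 111%) and the granule list 17.4% (9.44 to 22.7%). From day 4 to day 6 the lower of the B cell and erythroid medians was 2.05. Other marrow cells in the day 6 gate thus remain a candidate source for part of the rise. Median log2 fold changes of day 6 against untreated over the genes of each chromosome lay between −0.12 (X) and 0.114 (chromosome 1). A small share of other cells would move the median of a chromosome lost from the leukaemia only little, so these values do not decide this. The B cell and erythroid genes lay near the floor at day 4. The B cell genes summed to 74.5 and 89.2 CPM at day 6, against 103 and 52.6 CPM in untreated cells. The erythroid genes summed to 55.2 and 84.0 CPM, against 19.8 and 9.48 CPM. Spi1 also rose by 1.18 on the log2 scale over this interval, which does not tell other marrow cells from PU.1 restoration. PU.1 restoration, which the design names, stays open as an untested explanation, since gate and time changed together.

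The high share of a few RNAs in day 2 replicate 1 may be non-polyadenylated RNA carried into that library. Rn7sk, Rpph1, Rmrp, mt-Rnr1 and mt-Rnr2 were at a median of 38.8 times the highest other library, with 3.39 and 3.34 for the last 2, but these genes show the pattern themselves and decide nothing. Of 7 replication histone genes, whose messages mostly lack a poly(A) tail, the median was 0.876 times the highest untreated or day 2 replicate 2 library (quartiles 0.806 to 2.29), which leaves this open. A response to 2 days of Dox is opposed by day 2 replicate 2, where the same genes were at a median of 0.975 times the untreated mean.

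Of 4 transcripts chosen after their values were seen, each was higher in untreated replicate 2 than in replicate 1. Malat1 stood at 88.4 and 215 CPM, Neat1 at 27.2 and 50.9, Xist at 25.5 and 92.7, and Ankrd11 at 115 and 227, with ratios of 2.44, 1.87, 3.64 and 1.98 of replicate 2 to replicate 1. Median differences between replicates over the genes of each of 20 chromosomes lay between −0.07 and 0.05 on the log2 scale.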
